A study of Mus musculus with 9 samples.

How the data were processed

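The deposited files hold counts of reads per gene for each library, per the submitters' processing notes, which name the STAR aligner, HTSeq and the mouse genome build mm10. The notes give no versions and do not say which tool made which column. Each file has the layout of STAR's count output, with an unstranded column and a column for each strand, and does not name its annotation release. Per the labels the tissue was primary glioblastoma, total RNA was extracted with a Qiagen RNeasy kit, and libraries followed Illumina's instructions.

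The counts of the strand that held most reads were used, because the other strand held 3.25 to 3.64% of the reads in genes. The 4 summary lines at the head of each file were left out. Of 46517 gene identifiers 46005 matched the GENCODE vM21 annotation on GRCm38, which gave symbols, gene types and coordinates, and the other 512 kept their identifiers. Reads not counted in a gene (unmapped, multimapping, ambiguous or assigned to no gene) made up 17.9 to 27.3% of each library. Those assigned to no gene on the counted strand made up 4.89 to 14.9%. Mitochondrially encoded genes held 1.60 to 2.76% of the counts in genes. CPM were computed here from the deposited counts, as counts scaled to a common library total with TMM size factors.

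Genes were kept by edgeR's filterByExpr with the model as group. Counts were normalised with TMM and tested in edgeR 4.0.16 (R 4.3.3) with a negative binomial quasi-likelihood fit of the 3 models in all 9 libraries, 2-sided, with Benjamini-Hochberg adjustment over the 17947 genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.612, and 0.503 without Synapsin-cre replicate 1. Gene lists, fixed before the data were examined, numbered 43. The sex-linked list was used for values only, and the other 42 were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. Members of a list were also adjusted over the list alone.

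Named genes followed a rule fixed before the data were examined. For each comparison these were the 8 largest changes in each direction among genes that passed with a mean log2 CPM of at least 1 and no overlap between models, or, where fewer than 3 passed, the 3 smallest p in that direction. Up to 4 members of each called list, the 6 smallest p among the 3 models and a panel of 10 genes were added. Predicted genes, pseudogenes, immunoglobulin and T cell receptor genes and sex-linked genes were left out of that choice. The rule gave 184 genes and was also applied, once that library was seen to stand apart, in the fit without Synapsin-cre replicate 1. Not every gene that met the rule is reported. Genes said in the text to be chosen after their values were seen fall outside it.

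The alternatives were relative log expression and upper quartile size factors, a filter of 1 CPM in 3 libraries, no filter, limma voom with and without sample quality weights, DESeq2 1.42.0, the unstranded counts, fits of 2 models only, and fits that each left 1 library out. The choice of these was made before the data were examined, except for the fits of 2 models that also left Synapsin-cre replicate 1 out. Among these, the fit without that replicate and the fit of 2 models only are reported at length because of what was seen in the data, and the test fixed as the main one is that of all 9 libraries. Similarity between libraries was measured as Spearman correlation and as the share of variance in log2 CPM (prior count 2) explained by model, with an exact permutation test. Runs of neighbouring genes were sought as running medians over 7 genes of the log2 ratio to the median of the other 8 libraries, among genes of at least 2 CPM on average, against 1000 shuffles of gene order. Windows above every shuffled value were joined into a run where their first genes began within 3 Mb of each other.

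Planted changes were used as a self-test, with 100 genes at each size. edgeR recovered 19, 12 and 16% of 4-fold changes and 87, 67 and 82% of 16-fold changes in the 3 comparisons, with 4, 5 and 8 false calls. DESeq2 made 81 false calls among 234, 79 among 228 and 89 among 239, and its counts are therefore given only beside edgeR's. With a 4-fold change planted in the astrocyte list, camera called that list and 0 of 41 others. Genes were drawn independently in that simulation, whereas members of real lists moved together (estimated correlation 0.92 for proliferation with all 9 libraries). The 0 of 41 therefore does not show how often camera at the preset correlation overcalls in these data. With a run of 12 genes planted at an 8-fold change in 1 library, the scan found 1 run there that held all 12, and 0 runs in the other 8 libraries. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.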

Results

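Gene expression was measured by bulk RNA sequencing of glioblastoma tissue from 3 mouse models, with 3 samples per model and 9 libraries in all. Each model is named for a Cre recombinase line. Synapsin-cre takes its name from a promoter active in neurons, and Nestin-creERT2 from a promoter active in neural stem and progenitor cells. NG2-creERTM takes its name from the promoter of Cspg4, which is active in oligodendrocyte precursor cells and pericytes. The ERT2 and ERTM forms of Cre act once tamoxifen is given. The labels give the tissue, a mixed strain background and the model, and the series asks how tumours that represent different cells of origin compare. They do not name the tumour-driving alleles, the tumour site, or the age or sex of the animals. Replicates here are samples that the labels number separately within a model. The labels do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Sex-linked genes, given below, show that NG2-creERTM replicates 2 and 3 were not repeats of 1 animal. Replicate 1 also differed from replicate 2 in them (Xist 0.989 against 1320 CPM, Ddx3y 5.54 against 0.0523 CPM), though its Y-linked levels were low. The libraries held from 23557398 (Synapsin-cre replicate 1) to 41099967 (Nestin-creERT2 replicate 3) counts in genes, with a median of 34742585. In all, 17947 genes had enough counts to be tested.

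The tumours of one model resembled each other closely in Nestin-creERT2 and NG2-creERTM, and less so in Synapsin-cre. Spearman correlations across genes ranged from 0.948 to 0.957 within Nestin-creERT2, from 0.940 to 0.946 within NG2-creERTM and from 0.778 to 0.939 within Synapsin-cre. Synapsin-cre replicate 1 stood apart, with correlations of 0.778 to 0.884 with the other 8 libraries, against 0.891 to 0.957 among the remaining 28 pairs. That library carried high levels of mature neuronal genes, such as Syn1, which encodes synapsin, at 602 CPM (counts scaled to a common total per library) against 34.4 and 28.7 in replicates 2 and 3. Its dividing-cell genes were low, with a mean log2 CPM of 3.23 for the proliferation list against 6.16 to 7.35 in the other 8 libraries. Model explained 34.6% of the variance between libraries, with p = 0.118 in an exact permutation test over all 280 splits into 3 groups of 3. In that test 33 splits were as large, and the smallest possible p was 0.00357. Without Synapsin-cre replicate 1 the share was 50.8%, with an exact permutation p of 0.00357, the smallest that test can give. Without Synapsin-cre replicate 3 it was 42.1%, with an exact permutation p of 0.0107. Leaving out any other single library gave shares of 33.4 to 38.4%, with exact permutation p from 0.136 to 0.243.

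**Figure D1:**
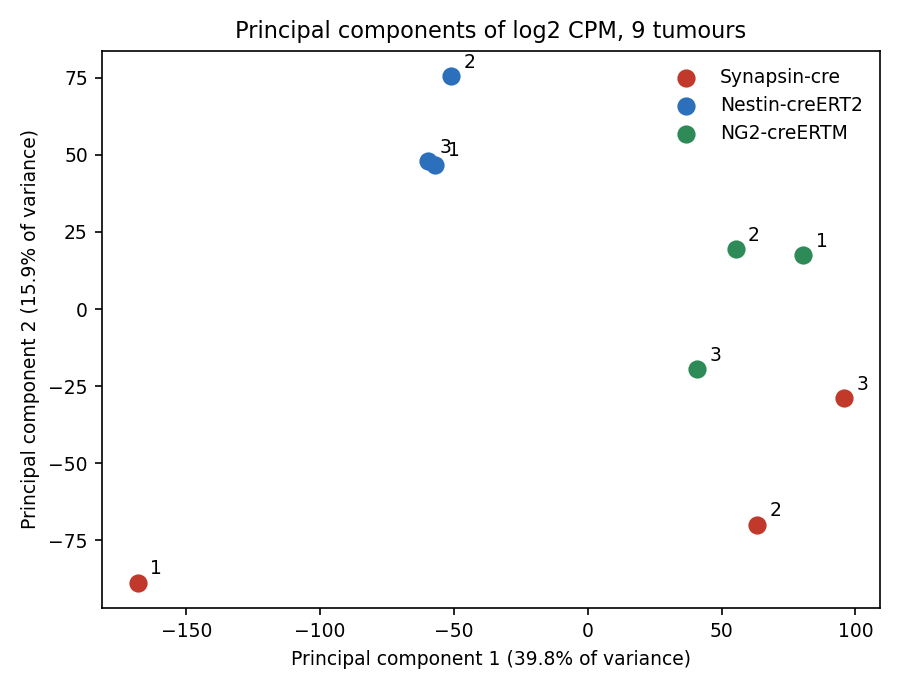
Principal components 1 (39.8% of the variance) and 2 (15.9%) of log2 CPM, with each point a library, coloured by model and numbered by replicate. Synapsin-cre replicate 1 lies alone at the left, and the Nestin-creERT2 libraries lie together at the top.

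None of the genes that name the Cre lines was highest in every library of its own line. Nes, which encodes the progenitor filament nestin, averaged 371 ± 275 CPM in Synapsin-cre, 439 ± 78.8 CPM in Nestin-creERT2 and 443 ± 214 CPM in NG2-creERTM (SD, n = 3 each). Cspg4, the gene for the NG2 proteoglycan, averaged 269 ± 236, 295 ± 293 and 498 ± 400 CPM in the same order. Syn1 averaged 222 ± 329, 94.5 ± 42.3 and 20.9 ± 11.3 CPM, and all 3 NG2-creERTM libraries lay below all 3 Nestin-creERT2 libraries in Syn1. Nf1, a brake on Ras signalling, averaged 136 ± 42.5, 54.1 ± 4.71 and 65.5 ± 32.0 CPM. Trp53, which encodes p53, averaged 148 ± 145, 76.6 ± 28.5 and 114 ± 20.3 CPM. Glial genes of the same fixed panel were present in every library. The growth factor receptor gene Pdgfra ranged from 128 to 2024 CPM, the lineage factor Olig2 from 39.0 to 809 CPM and the astrocyte filament Gfap from 94.1 to 4023 CPM. Egfr, the epidermal growth factor receptor, was the member of the panel with the largest contrast, at 717 ± 804 CPM in Nestin-creERT2 against 10.9 ± 13.2 CPM in Synapsin-cre and 12.1 ± 6.44 CPM in NG2-creERTM. All 3 Nestin-creERT2 libraries (193 to 1643 CPM) exceeded the other 6 (2.01 to 26.0 CPM). None of these genes passed in any of the 3 comparisons of all 9 libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

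Expression of sex-linked genes followed the models only in part. Xist, the RNA that silences an X chromosome in female cells, lay between 778 and 1810 CPM in the 3 Nestin-creERT2 libraries and near 1 CPM in the 3 Synapsin-cre libraries, where the Y-linked genes Ddx3y (59.2 to 66.9 CPM) and Kdm5d (57.8 to 70.2 CPM) were present. Among NG2-creERTM libraries, replicate 2 had Xist at 1320 CPM, replicate 3 had Ddx3y at 71.7 CPM, and replicate 1 had neither at such levels (Xist 0.989 CPM, Ddx3y 5.54 CPM). Sex-linked expression and model therefore coincided completely between Synapsin-cre and Nestin-creERT2.

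Synapsin-cre replicate 2 and NG2-creERTM replicate 3 each had a run of neighbouring genes at high levels around Met, the hepatocyte growth factor receptor gene, on chromosome 6. The region was chosen after its values were seen. Met reached 9037 CPM in Synapsin-cre replicate 2 and 5707 CPM in NG2-creERTM replicate 3, against 4.34 to 40.1 CPM in the other 7 libraries. Capza2, an actin capping protein gene beside it, reached 8840 and 18564 CPM in those libraries. The run held 9 genes from 17463800 to 18879586 in Synapsin-cre replicate 2, and 10 genes from 17065149 to 18514843 in NG2-creERTM replicate 3. The rule for runs took in Tes, Cav2 and Cav1 in NG2-creERTM replicate 3, at log2 ratios of only 1.97, 0.59 and 0.63. Cav2 and Cav1 lay there within the range of the other libraries. The genes from Met to Cttnbp2 had log2 ratios of at least 4.64 in that library.

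**Figure D2:**
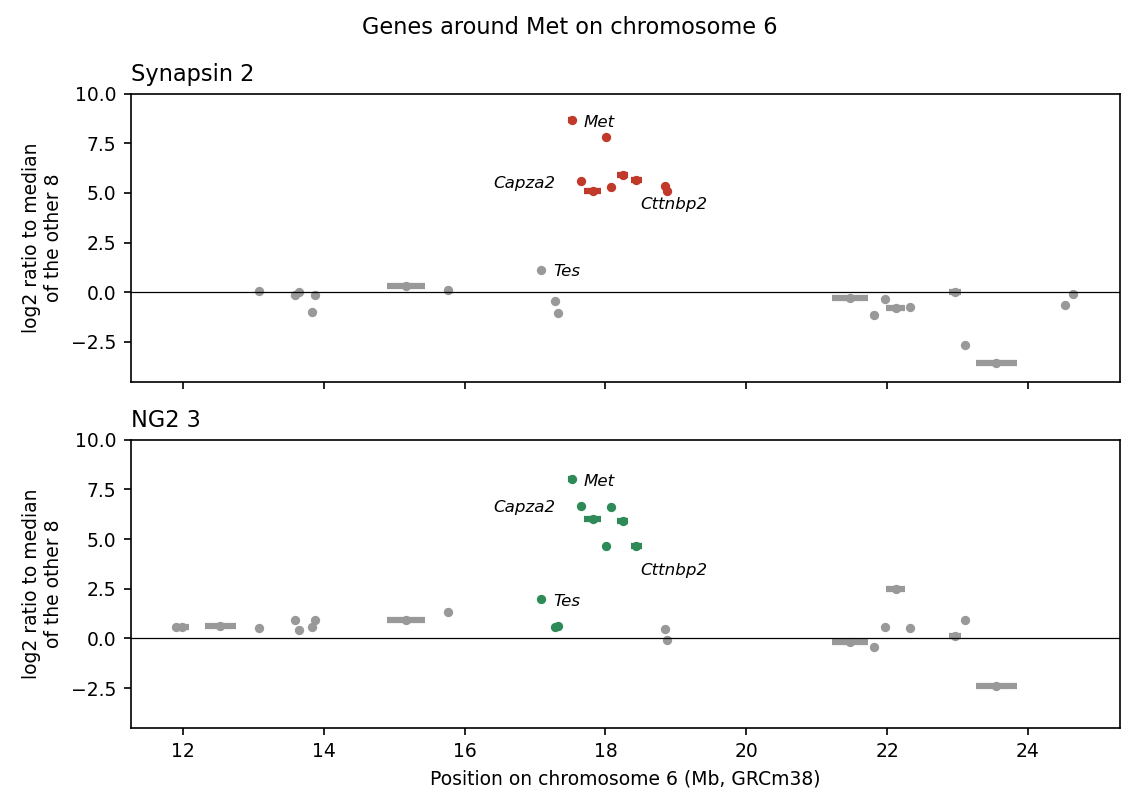
log2 ratio of CPM to the median of the other 8 libraries for genes along chromosome 6 (GRCm38 position in Mb), in Synapsin-cre replicate 2 and NG2-creERTM replicate 3, with genes of the run coloured and their neighbours grey. Met and Capza2 stand high in both libraries, and the medians of the flanking genes lie between -0.69 and 0.61.

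The comparison of NG2-creERTM with Nestin-creERT2 sets tumours named for oligodendrocyte precursor cells against tumours named for neural stem cells. NG2-creERTM tumours had more RNA from genes of the Schwann cell and neural crest lineage, of fibroblasts and of vessel walls, and less from genes of neurons, astrocytes and the forebrain. These are calls of camera at a preset correlation. An estimated correlation or fry called 0 of 42 lists with all 9 libraries. The fit without Synapsin-cre replicate 1 had 0 with an estimated correlation, and fry called 3, all lower: astrocyte (fry adjusted p = 0.0376), pan-neuronal (0.0407) and forebrain transcription factor genes (0.0481). Foxd3, a neural crest transcription factor (chromosome 4, 99656299 to 99658622), averaged 29.9 ± 23.7 CPM against 0.160 ± 0.110 CPM in Nestin-creERT2 (SD, n = 3). In the other direction Agt, which encodes angiotensinogen and is made by astrocytes (chromosome 8, 124556534 to 124569706), averaged 26.0 ± 5.27 against 324 ± 167 CPM. Slc1a2, the main astrocytic glutamate transporter, averaged 110 ± 43.9 against 957 ± 226 CPM.

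With all 9 libraries in the fit, 0 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.102; 2021 genes at an unadjusted p under 0.05, 992 higher and 1029 lower). limma voom passed 0 and DESeq2 623. With the 6 libraries of these models alone, which leaves out the spread among the Synapsin-cre tumours, edgeR's adjusted test passed 237 genes, 54 higher and 183 lower. Without Synapsin-cre replicate 1 it passed 124, of which 122 were among the 237. Both fits were planned as alternatives to the fit of all 9 libraries, and they are given in detail because that fit passed 0 genes, a choice made after the results were seen.

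Of the Schwann cell and peripheral nerve list, 11 of 13 measured members had positive fold changes (median log2 fold change 2.92, camera adjusted p = 1.7e-06, adjusted p = 0.364 with an estimated correlation). None of its members passed over all genes with 9 libraries and 6 did adjusted over the list alone. In the fit of 6 libraries 4 members rose over all genes tested. They included Foxd3 (log2 fold change 7.52 ± 0.86 SE, edgeR adjusted p = 0.0354). Erbb3, the receptor through which neuregulin acts on Schwann cells (chromosome 10, 128567523 to 128589652), rose by 6.82 ± 0.90 (edgeR adjusted p = 0.0354), and Dhh, a hedgehog signal made by Schwann cells, by 6.54 ± 1.06 (adjusted p = 0.0436). Dct, a pigment cell enzyme gene, also rose there by 6.31 ± 0.97 (edgeR adjusted p = 0.0397).

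Of the fibroblast and meningeal list, 11 of 14 members had positive fold changes (median 2.93, camera adjusted p = 2.09e-07, adjusted p = 0.310 with an estimated correlation). Over all genes 0 passed with 9 libraries, against 9 adjusted over the list alone. The fibrillar collagen gene Col3a1 (log2 fold change 4.49 ± 0.69, edgeR adjusted p = 0.0397) and Mgp, an inhibitor of calcification (4.64 ± 0.63, edgeR adjusted p = 0.0388), rose in the fit of 6 libraries. Of the pericyte and smooth muscle list 11 of 14 members were positive (median 1.45, camera adjusted p = 1.11e-05, adjusted p = 0.323 with an estimated correlation; 7 members adjusted over the list alone). Mcam, an adhesion molecule of vessel walls, rose by 3.58 ± 0.65 in the fit of 6 libraries (edgeR adjusted p = 0.0466). The endothelial list was also higher (11 of 14 members, median 0.82, camera adjusted p = 0.00011, adjusted p = 0.548 with an estimated correlation; 1 member adjusted over the list alone). Extracellular matrix remodelling was too (18 of 20, median 0.56, camera adjusted p = 0.000451, adjusted p = 0.552 with an estimated correlation; 2 members adjusted over the list alone). For matrix remodelling Nestin-creERT2 replicate 1 had a mean log2 CPM of 6.51, within the NG2-creERTM range of 5.64 to 6.70. Postn, a matrix protein gene, rose by 5.14 ± 0.95 in the fit of 6 libraries (edgeR adjusted p = 0.0485).

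All 18 members of the pan-neuronal and synaptic list were lower in NG2-creERTM (median log2 fold change -2.52, camera adjusted p = 1.3e-09, adjusted p = 0.399 with an estimated correlation). In 17 of them every NG2-creERTM library lay below every Nestin-creERT2 library, where chance alone separates 10% of genes, both directions together. Members of this list moved together (estimated correlation 0.68 with all 9 libraries), so the 17 are not independent of each other. With 9 libraries 0 members passed over all genes and 1 adjusted over the list alone. In the fit of 6 libraries 6 passed over all genes and 17 adjusted over the list alone. Among those 6 was Nefm, a neurofilament subunit, which fell by 3.61 (SE 0.59, edgeR adjusted p = 0.0436). Thy1, a surface protein of mature neurons, fell by 3.47 (SE 0.64, edgeR adjusted p = 0.0485), and Elavl4, an RNA-binding protein of neurons, fell by 1.99 (SE 0.28, edgeR adjusted p = 0.0388). The list of glutamatergic neurons was lower too (12 of 14 members negative, median -2.68, camera adjusted p = 0.00155, adjusted p = 0.550 with an estimated correlation). That of GABAergic neurons was also lower (14 of 15, median -2.02, camera adjusted p = 0.000475, adjusted p = 0.550 with an estimated correlation), with 0 members adjusted over either list alone in 9 libraries. Penk, the precursor of the enkephalin opioid peptides, fell by 6.13 in the fit of 6 libraries (SE 1.02, edgeR adjusted p = 0.0445). All 12 forebrain transcription factors had negative fold changes (median -1.81, camera adjusted p = 0.000697, adjusted p = 0.399 with an estimated correlation; 1 member adjusted over the list alone). Lhx2, a patterning factor of the cortex, fell by 1.90 in the fit of 6 libraries (SE 0.30, edgeR adjusted p = 0.0397).

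Astrocyte genes were lower in NG2-creERTM for 15 of 16 members (median -1.78, camera adjusted p = 1.27e-05, adjusted p = 0.399 with an estimated correlation; 0 over all genes and 2 adjusted over the list alone). In the fit of 6 libraries Slc1a2 fell by 3.13 (SE 0.41, edgeR adjusted p = 0.0354) and Agt fell by 3.64 (SE 0.46, edgeR adjusted p = 0.0354). Sox9, a glial transcription factor that also stands in the stem cell and classical lists, fell by 2.23 (SE 0.33, edgeR adjusted p = 0.0397). Egfr (chromosome 11, 16752203 to 16918158) fell by 5.88 in the same fit (SE 0.99, edgeR adjusted p = 0.0445), and Draxin, a repulsive axon guidance protein, fell by 4.55 (SE 0.52, edgeR adjusted p = 0.0354). The classical glioblastoma list, which includes Egfr and Sox9, was not called with all 9 libraries (camera adjusted p = 0.107, median -0.08).

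Stress and metabolic groups were higher in NG2-creERTM. Of the hypoxia and glycolysis list 17 of 19 members were positive (median 1.27, camera adjusted p = 6.35e-05, adjusted p = 0.550 with an estimated correlation). The stress protein gene Ndrg1 averaged 175 ± 37.4 against 35.1 ± 26.0 CPM and carbonic anhydrase Car9 25.4 ± 26.3 against 1.46 ± 1.41 CPM. The mesenchymal glioblastoma list was higher as well (18 of 22, median 0.70, camera adjusted p = 0.00016, adjusted p = 0.550 with an estimated correlation). So were the immediate-early genes (11 of 14, median 0.83, camera adjusted p = 0.0157, adjusted p = 0.552 with an estimated correlation). Of the mesenchymal members Met rested on NG2-creERTM replicate 3 (5707 CPM, against 9.26 and 26.9 CPM in the other 2). For the mesenchymal list Nestin-creERT2 replicate 1 had a mean log2 CPM of 5.86, within the NG2-creERTM range of 5.49 to 6.08. The list of nuclear oxidative phosphorylation was called higher (14 of 18, median 0.34, camera adjusted p = 0.0157, adjusted p = 0.361 with an estimated correlation). Cholesterol synthesis was called higher (15 of 18, median 0.27, camera adjusted p = 0.0205, adjusted p = 0.552 with an estimated correlation), and erythrocytes were (5 of 5, median 0.70, camera adjusted p = 0.0313, adjusted p = 0.552 with an estimated correlation). With all 9 libraries no member of these 6 lists passed adjusted over the list alone. In the fit of 6 libraries 8 hypoxia and glycolysis members and 2 immediate-early members did, all higher. The choroid plexus list was called lower (8 of 9, median -7.33, camera adjusted p = 0.0417, adjusted p = 0.736 with an estimated correlation; 7 members adjusted over the list alone). It rested on Nestin-creERT2 replicate 1, in which its mean log2 CPM was 5.96 against at most 0.32 elsewhere. In all, 17 of 42 lists were called by camera with all 9 libraries, 11 higher and 6 lower. There were 0 with an estimated correlation (lowest adjusted p = 0.310) or by fry (lowest adjusted p = 0.0522).

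**Figure D3:**
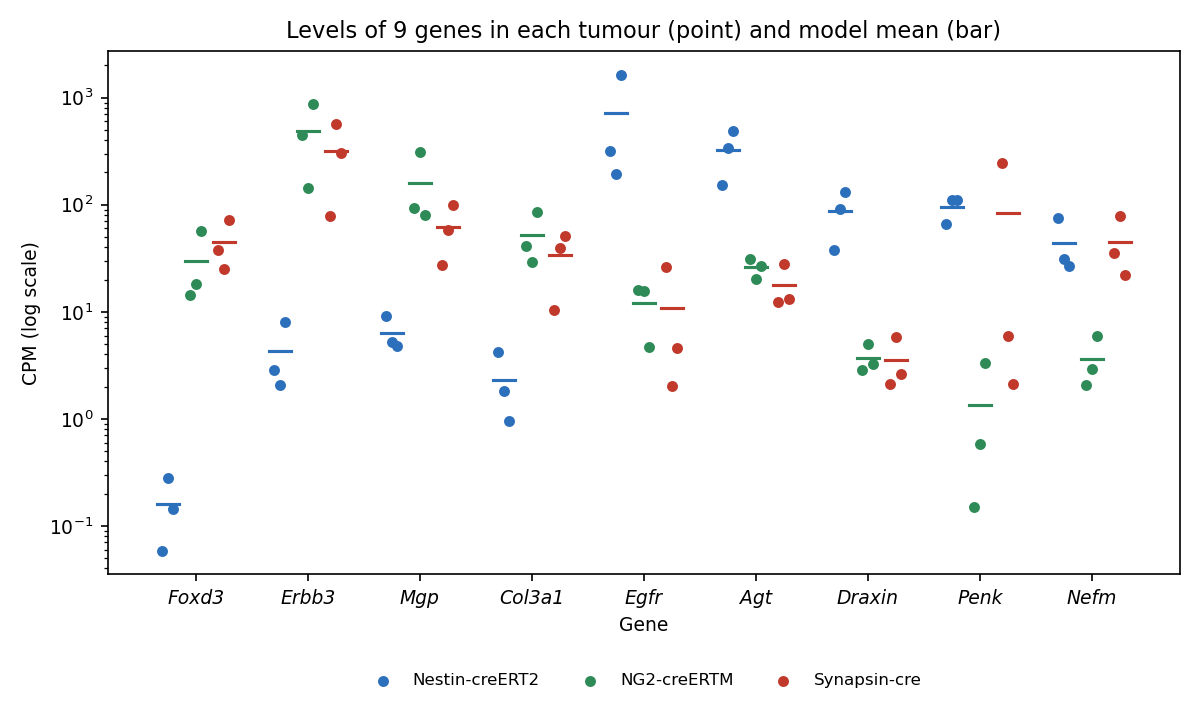
CPM on a log scale of 9 genes in each library (points) with the mean of each model (bars), for Nestin-creERT2, NG2-creERTM and Synapsin-cre. Foxd3 and Erbb3 sit below 10 CPM in all Nestin-creERT2 libraries, Egfr, Agt and Draxin sit highest there, and Penk in Synapsin-cre rests on replicate 1.

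The comparison of Synapsin-cre with Nestin-creERT2 sets tumours named for neurons against tumours named for neural stem cells. Synapsin-cre tumours had more RNA from Schwann and neural crest genes and fibroblast genes, and less from progenitor genes. Replicates 2 and 3 also had more from hypoxia genes and less from astrocyte and pan-myeloid genes, while replicate 1 did not. These are calls of camera at a preset correlation. An estimated correlation or fry called 0 of 42 lists with all 9 libraries. The fit without Synapsin-cre replicate 1 had 0 with an estimated correlation, and fry called 3, all lower: astrocyte (fry adjusted p = 0.0101), pan-myeloid (0.0227) and microglial genes (0.0227). Foxd3 averaged 45.3 ± 24.7 CPM against 0.160 ± 0.110 CPM (SD, n = 3; log2 fold change 8.11 ± 0.91 SE). Erbb3 averaged 317 ± 246 against 4.33 ± 3.26 CPM (6.19 ± 1.04). Agt averaged 17.7 ± 8.67 against 324 ± 167 CPM (-4.20 ± 0.53), Draxin 3.54 ± 2.02 against 86.5 ± 47.4 CPM (-4.61 ± 0.62), and Egfr had a log2 fold change of -6.05 ± 1.28. Sex-linked genes differed between these models as well, and none of these differences is separate from them.

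No gene passed among all 9 libraries. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 0 (lowest adjusted p = 0.118; 1937 genes at an unadjusted p under 0.05, 1210 higher and 727 lower). limma voom passed 0 and DESeq2 497. Without Synapsin-cre replicate 1 edgeR's adjusted test passed 273 genes, 75 higher and 198 lower. With the 6 libraries of both models it passed 5, all of the sex-linked list: Xist (-10.05), Kdm5d (11.07), Eif2s3y (10.70), Uty (10.33) and Ddx3y (11.02). Of those 5, 0 were among the 273. Without that replicate Foxd3 (8.21, edgeR adjusted p = 0.0198), Erbb3 (6.65, edgeR adjusted p = 0.0242) and Clca3a1, a gene of the calcium-activated chloride channel regulator family with near copies beside it on chromosome 3 (6.47, edgeR adjusted p = 0.0198), rose. Egfr (-7.77, edgeR adjusted p = 0.0341), Agt (-3.99, edgeR adjusted p = 0.0292) and Draxin (-4.34, edgeR adjusted p = 0.0293) fell.

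The Schwann cell and peripheral nerve list was higher with and without that replicate: 12 of 13 members were positive (median 1.96, camera adjusted p = 0.000103, adjusted p = 0.535 with an estimated correlation; 0 over all genes and 5 adjusted over the list alone). Without it the median was 1.94 (camera adjusted p = 0.000668, adjusted p = 0.357 with an estimated correlation). Fibroblast and meningeal genes were positive for 12 of 14 members (median 2.33, camera adjusted p = 0.000216, adjusted p = 0.471 with an estimated correlation; 6 adjusted over the list alone). Col3a1 averaged 33.6 ± 20.9 against 2.32 ± 1.69 CPM and Mgp 61.4 ± 35.5 against 6.39 ± 2.39 CPM. Without replicate 1 their median was 1.03 (camera adjusted p = 0.00304, adjusted p = 0.341 with an estimated correlation). Endothelial genes were higher (12 of 14 positive, median 0.80, camera adjusted p = 0.00184, adjusted p = 0.610 with an estimated correlation; 0 adjusted over the list alone). So were pericyte and smooth muscle genes (11 of 14, median 0.90, camera adjusted p = 0.00854, adjusted p = 0.610 with an estimated correlation; 4 adjusted over the list alone), but neither list was called without replicate 1 (camera adjusted p = 0.116 and 0.0525). The mean voom log2 fold change went from 0.61 to 0.32 for endothelial genes and from 0.70 to 0.65 for pericyte and smooth muscle genes, so the lost call of the latter does not show that the difference rested on that replicate. Kcnj8 and Abcc9 of the pericyte list and Slco1a4 of the endothelial list lay within a run of 54 neighbouring genes on chromosome 6. That run was raised in Synapsin-cre replicate 3 (median log2 ratio 3.56), and how much it added to either list was not tested.

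Hypoxia and glycolysis genes were positive for 18 of 19 members (median 1.30, camera adjusted p = 2.27e-05, adjusted p = 0.610 with an estimated correlation). Replicate 1 had a mean log2 CPM of 5.53 for this list, within the Nestin-creERT2 range of 5.04 to 6.21. Among its members were Vegfa, the vascular growth factor (585 ± 459 against 102 ± 43.2 CPM), and the glucose transporter Slc2a1 (296 ± 125 against 112 ± 54.0 CPM). The immediate-early genes were called higher (13 of 14, median 1.21, camera adjusted p = 0.00157, adjusted p = 0.610 with an estimated correlation). So were the mesenchymal list (17 of 22, median 0.79, camera adjusted p = 0.00352, adjusted p = 0.610 with an estimated correlation) and extracellular matrix remodelling (13 of 20, median 0.49, camera adjusted p = 0.0279, adjusted p = 0.610 with an estimated correlation). With all 9 libraries no member of these 4 lists passed adjusted over the list alone. Without replicate 1, 11 hypoxia, 7 immediate-early and 1 matrix member passed higher in that way, and 1 immediate-early member lower. Nestin-creERT2 replicate 1 had a mean log2 CPM of 6.51 for matrix remodelling, above all Synapsin-cre libraries (4.71 to 6.36). For the mesenchymal list it had 5.86, within their range of 4.86 to 5.93. Met, a mesenchymal member, rested on Synapsin-cre replicate 2 (9037 CPM, against 40.1 and 24.5 CPM in the other 2).

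Astrocyte genes were negative for 12 of 16 members (median -0.76, camera adjusted p = 5.31e-06, adjusted p = 0.535 with an estimated correlation; 2 adjusted over the list alone). Synapsin-cre replicate 1 had as much astrocyte RNA as the Nestin-creERT2 tumours (mean log2 CPM 7.86 against 7.38 to 7.88), and without it the median was -2.76 (camera adjusted p = 1.41e-09, adjusted p = 0.157 with an estimated correlation). There 5 members passed over all genes. The neural stem and progenitor list was lower for 14 of 16 members (median -0.55, camera adjusted p = 0.000367, adjusted p = 0.471 with an estimated correlation; 2 adjusted over the list alone). The fatty acid binding protein gene Fabp7 averaged 142 ± 53.7 against 631 ± 214 CPM. The classical list was called lower (9 of 15 negative, median -0.24, camera adjusted p = 0.00854, adjusted p = 0.471 with an estimated correlation; 3 lower adjusted over the list alone). The proneural list was called lower (10 of 16, median -0.67, camera adjusted p = 0.0321, adjusted p = 0.610 with an estimated correlation; 1 higher and 2 lower adjusted over the list alone), and the oligodendrocyte precursor list was (12 of 16, median -0.81, camera adjusted p = 0.0231, adjusted p = 0.610 with an estimated correlation; 1 adjusted over the list alone). None of these 3 was called without replicate 1. The mean voom log2 fold change of the classical list stayed the same (-0.95 with and without it, camera adjusted p = 0.0687 without), so that difference did not rest on replicate 1. It went from -0.57 to -0.09 for the proneural list and from -0.53 to 0.04 for the oligodendrocyte precursor list. Erbb3 was the proneural member higher adjusted over the list alone.

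Pan-myeloid and microglial genes were lower in Synapsin-cre replicates 2 and 3, while the macrophage and neutrophil lists were not called. Replicate 1 went the other way, above every Nestin-creERT2 library in mean log2 CPM (5.77 against 5.19 to 5.61 for pan-myeloid genes and 5.74 against 4.63 to 5.01 for microglia). Of the pan-myeloid and complement list 12 of 14 members were negative (median -0.97, camera adjusted p = 1.03e-05, adjusted p = 0.610 with an estimated correlation; 0 adjusted over the list alone). Without replicate 1 all 14 were (median -2.02, camera adjusted p = 2.67e-10, adjusted p = 0.341 with an estimated correlation; 13 adjusted over the list alone). In that fit the complement gene C1qa (-2.57, edgeR adjusted p = 0.0292), the signalling adaptor Tyrobp (-2.33, edgeR adjusted p = 0.0276) and its partner receptor Trem2 (-3.02, edgeR adjusted p = 0.0268) fell. The microglia list had a median of -0.16 with all 9 libraries (9 of 14 negative, camera adjusted p = 0.0104, adjusted p = 0.610 with an estimated correlation) and of -2.07 without replicate 1 (camera adjusted p = 5.49e-06, adjusted p = 0.341 with an estimated correlation). B cell and plasma cell genes were lower too (7 of 8, median -0.95, camera adjusted p = 0.00936, adjusted p = 0.610 with an estimated correlation), with 0 members of either list adjusted over the list alone in 9 libraries. The lists of bone marrow derived macrophages and monocytes (11 of 15 positive, median 0.79, camera adjusted p = 0.154) and neutrophils (6 of 8 positive, median 0.93, camera adjusted p = 0.126) were not called. MHC class II and interferon response genes were called lower only without replicate 1. Their medians there were -1.54 (camera adjusted p = 0.0271, adjusted p = 0.705 with an estimated correlation) and -0.95 (camera adjusted p = 0.00537, adjusted p = 0.728 with an estimated correlation).

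For neuronal genes the library decided the direction. The pan-neuronal list had a positive median (0.54) while camera, which reads the mean of log values, called it lower (camera adjusted p = 0.00581, adjusted p = 0.610 with an estimated correlation). The glutamatergic list did likewise (median 0.30, camera adjusted p = 0.00444, adjusted p = 0.610 with an estimated correlation). Without Synapsin-cre replicate 1 the medians were -1.77 (camera adjusted p = 8.05e-10, adjusted p = 0.341 with an estimated correlation) and -3.79 (camera adjusted p = 6.95e-06, adjusted p = 0.341 with an estimated correlation). The GABAergic list was called at -2.52 (camera adjusted p = 2.56e-05, adjusted p = 0.341 with an estimated correlation). Ralyl, an RNA-binding protein gene, had a log2 fold change of 0.49 with all 9 libraries and fell by 7.26 without that replicate (edgeR adjusted p = 0.0293). The Hox cluster list was called lower on the same library (7 of 8 negative, median -0.95, camera adjusted p = 0.0321, adjusted p = 0.610 with an estimated correlation). So was the proliferation list (14 of 24, median -0.12, camera adjusted p = 0.0142, adjusted p = 0.683 with an estimated correlation). Without it the Hox list was not called (camera adjusted p = 0.987) and proliferation was called higher (median 0.40, camera adjusted p = 0.0123, adjusted p = 0.728 with an estimated correlation). In all, 20 of 42 lists were called by camera with all 9 libraries, 8 higher and 12 lower. There were 0 with an estimated correlation (lowest adjusted p = 0.471) or by fry (lowest adjusted p = 0.147).

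**Figure D4:**
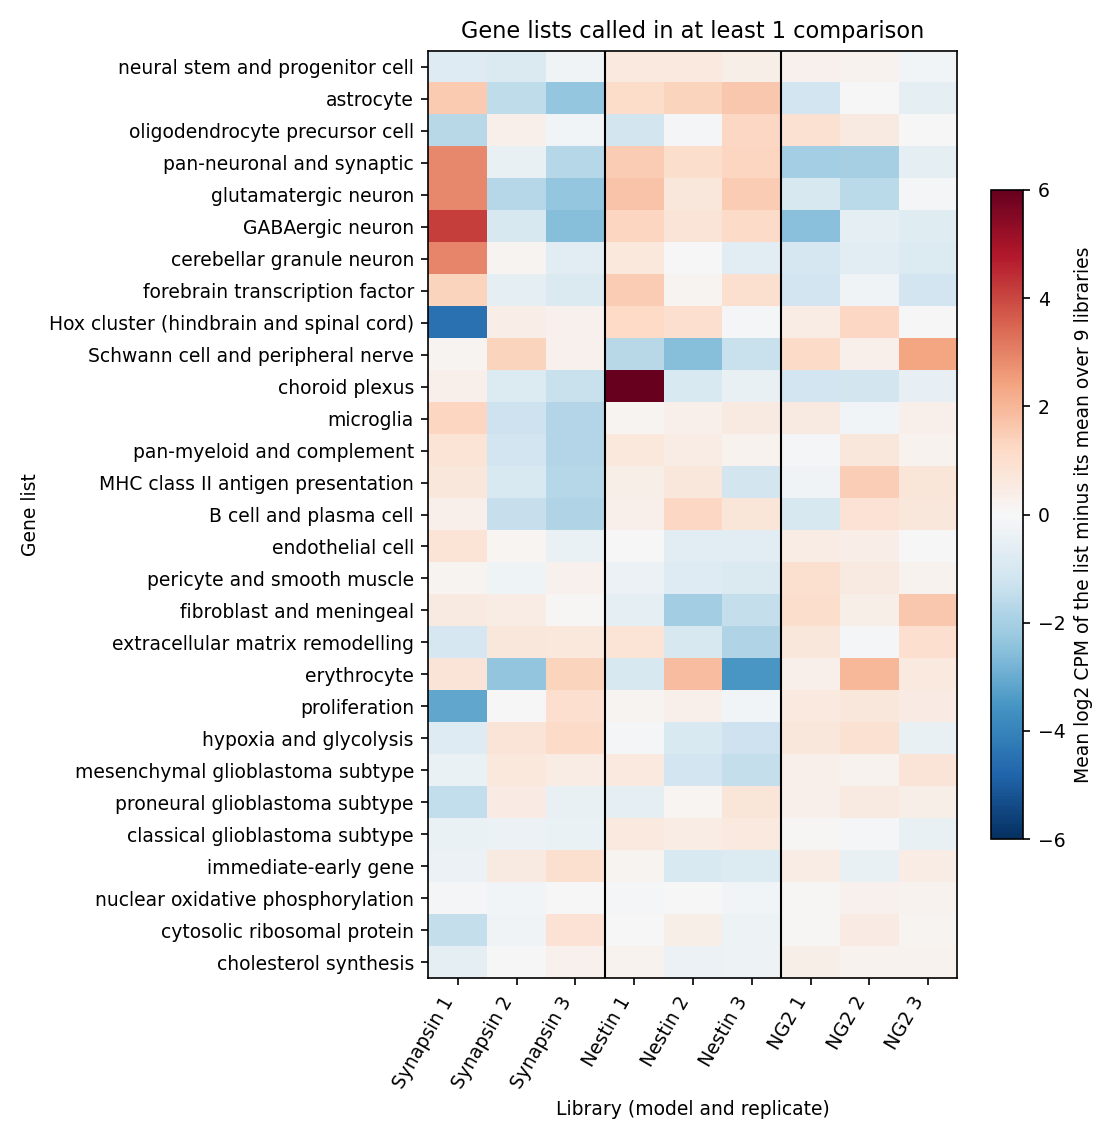
Mean log2 CPM of the members of each gene list called in at least 1 comparison, minus the list's mean over the 9 libraries, by library (columns, grouped by model). Synapsin-cre replicate 1 is highest for the neuronal lists and lowest for proliferation and Hox genes, and the Schwann list is lowest in the 3 Nestin-creERT2 libraries.

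The comparison of Synapsin-cre with NG2-creERTM sets tumours named for neurons against tumours named for oligodendrocyte precursor cells. Camera called fewer lists here than in the other comparisons, and what separated them in all 9 libraries rested in large part on Synapsin-cre replicate 1. Nefm, a neurofilament subunit gene, was higher in Synapsin-cre without passing, between 22.0 and 78.2 CPM against 2.07 to 5.88 CPM (n = 3; log2 fold change 3.64 ± 0.68 SE, and 3.79 without replicate 1). Genes of antigen presentation were lower, with H2-Ab1, an MHC class II chain, at 10.5 ± 5.44 against 67.9 ± 30.9 CPM (SD, n = 3; -2.69 ± 0.84). Esr1, the oestrogen receptor (chromosome 10, 4611593 to 5005614), averaged 1.01 ± 0.590 against 42.3 ± 23.1 CPM (-5.40 ± 0.76), and the voltage-gated calcium channel gene Cacna1a 148 ± 64.8 against 35.3 ± 7.16 CPM (2.07 ± 0.37).

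None of these passed. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 0 genes (lowest adjusted p = 0.357; 2298 at an unadjusted p under 0.05, 1581 higher and 717 lower). limma voom passed 0 and DESeq2 446. Without Synapsin-cre replicate 1 it passed 1, Rps3a3 (7.01 ± 0.65 SE, edgeR adjusted p = 0.0319), annotated as a processed pseudogene of a ribosomal protein gene and chosen here after its values were seen. It lay at 52.6 and 132 CPM in Synapsin-cre replicates 2 and 3 against at most 1.25 CPM elsewhere, and its reads cannot be told firmly from those of near copies.

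All 18 pan-neuronal genes were higher in Synapsin-cre (median 3.30, camera adjusted p = 0.000204, adjusted p = 0.699 with an estimated correlation; 0 over all genes and 3 adjusted over the list alone). Without replicate 1 the median was 0.12 and the list was not called (camera adjusted p = 0.198). The cerebellar granule neuron list was higher for 7 of 8 members (median 2.91, camera adjusted p = 0.0226, adjusted p = 0.699 with an estimated correlation; 5 adjusted over the list alone) and was not called without it either (camera adjusted p = 0.318). Calb2, a calcium-binding protein of interneurons in that list, had a log2 fold change of 5.50, and -0.06 without replicate 1, while Reln, a secreted guide of neuronal migration, had 2.72 and 2.69.

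MHC class II, pan-myeloid and microglial genes were called lower with and without that replicate, but the direction held only in replicates 2 and 3. Replicate 1 lay above every NG2-creERTM library in mean log2 CPM for pan-myeloid genes (5.77 against 4.83 to 5.65) and microglia (5.74 against 4.31 to 4.98), and within their range for MHC class II genes (3.39 against 2.49 to 4.18). The MHC class II list was negative for 10 of 11 members (median -1.43, camera adjusted p = 0.00046, adjusted p = 0.699 with an estimated correlation). Without replicate 1 it was for 11 of 12 (median -2.10, camera adjusted p = 9.2e-06, adjusted p = 0.456 with an estimated correlation). The pan-myeloid list was negative for 12 of 14 (median -0.64, camera adjusted p = 6.24e-05, adjusted p = 0.699 with an estimated correlation). Without it all 14 were negative (median -1.72, camera adjusted p = 4.2e-15, adjusted p = 0.333 with an estimated correlation; 13 adjusted over the list alone). The microglia list had medians of -0.16 (8 of 14 negative and 6 positive, camera adjusted p = 0.0174, adjusted p = 0.699 with an estimated correlation) and, without replicate 1, of -2.04 (camera adjusted p = 9.1e-09, adjusted p = 0.333 with an estimated correlation). Trem2 averaged 8.72 ± 9.21 against 22.2 ± 4.18 CPM. The other immune lists were not called with all 9 libraries. Interferon response genes were positive for 18 of 18 (median 1.44, camera adjusted p = 0.309), and without replicate 1 negative for 17 of 18 (median -0.99, camera adjusted p = 0.0570). Macrophage and monocyte genes were positive for 10 of 15 (median 0.39, with a lower direction in camera, adjusted p = 0.749) and neutrophil genes for 6 of 8 (median 0.74, camera adjusted p = 0.520).

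Oligodendrocyte precursor genes were negative for 14 of 16 members (median -0.91, camera adjusted p = 0.000733, adjusted p = 0.699 with an estimated correlation), with Olig2 at 134 ± 110 against 361 ± 195 CPM. The proneural list was negative for 12 of 16 (median -0.53, camera adjusted p = 0.00458, adjusted p = 0.699 with an estimated correlation). All 24 proliferation genes were negative (median -0.49, camera adjusted p = 2.04e-05, adjusted p = 0.699 with an estimated correlation). So were all 8 Hox genes (median -1.04, camera adjusted p = 0.0395, adjusted p = 0.699 with an estimated correlation) and 17 of 22 ribosomal protein genes (median -0.18, camera adjusted p = 0.00458, adjusted p = 0.862 with an estimated correlation). None of these 5 lists was called without replicate 1. Nuclear oxidative phosphorylation genes were negative for 14 of 18 (median -0.33, camera adjusted p = 0.0147, adjusted p = 0.699 with an estimated correlation) and remained called without it (camera adjusted p = 0.0328, adjusted p = 0.456 with an estimated correlation). Apart from the neuronal lists, no list called in this comparison had a member that passed adjusted over the list alone in 9 libraries. In all, 11 of 42 lists were called by camera with all 9 libraries, 2 higher and 9 lower. There were 0 with an estimated correlation (lowest adjusted p = 0.699) or by fry (lowest adjusted p = 0.236). Without replicate 1 there were 9, of which 4 were among the 11.

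Among the 3 models together the genes with the smallest p included Draxin, Agt, Foxd3, Clca3a1 and Egflam, an extracellular matrix gene of synapses and muscle. Agt and Draxin were highest in Nestin-creERT2 and Foxd3, Clca3a1 and Egflam lowest there. Egflam averaged 51.9 ± 34.7 CPM in NG2-creERTM against 1.39 ± 0.252 CPM in Nestin-creERT2 (SD, n = 3). None passed, since edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment of both model coefficients passed 0 genes (lowest adjusted p = 0.103; 2353 at an unadjusted p under 0.05). limma voom passed 0 and DESeq2's likelihood ratio test 868. Without Synapsin-cre replicate 1 edgeR's adjusted test passed 346.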

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

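The tests of Synapsin-cre replicate 1, the Met region and the Schwann genes below were chosen after the result was seen, as were the brain region gene lists used in them.

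Of 50 measures compared among the 9 libraries with a Dixon rule, 7 set 1 library apart, and 4 of these were Synapsin-cre replicate 1. By chance the rule sets a library apart in 1 of 20 groups of values, so some of the 7 may be chance. That library had the fewest counts in genes (23.6 M, next 33.1 M), the highest cerebellar granule neuron score (mean log2 CPM 5.27, next 2.96), the lowest Hox score (-2.93, next 1.45) and the lowest proliferation score (3.23, next 6.16). Nestin-creERT2 replicate 1 had the highest choroid plexus score (5.96, next 0.32), Synapsin-cre replicate 2 the highest skeletal muscle score (0.30, next -0.65) and Synapsin-cre replicate 3 the lowest mitochondrially encoded score (9.69, next 10.4).

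Synapsin-cre replicate 1 stood apart from every other library. Lower sequencing depth is argued against, since after all libraries were thinned to its depth its highest Spearman correlation was 0.884, under the lowest of any other pair at 0.890. A wrong label on a Nestin-creERT2 tumour is undecided. Of 73 genes called higher in Synapsin-cre without it, 34.2% lay nearer the other Synapsin-cre libraries than Nestin-creERT2 in it. Foxd3 (38.1 CPM, at most 0.277 in Nestin-creERT2), Egfr (26.0, 193 to 1643), Agt (12.2, 151 to 484) and Xist (1.28, 778 to 1810) lay outside the Nestin-creERT2 range. These genes do not settle the label, because Xist follows the sex of the animal and not the Cre line. The levels of Foxd3, Egfr and Agt could also reflect tissue other than tumour in that sample. RNA from olfactory bulb tissue may be present, with a median log2 ratio of 4.59 to the other libraries and all 8 marker genes highest there, against at most 1.08 for cortex, striatum and hypothalamus genes. Th, which makes dopamine and was chosen after its value was seen, was at 273 CPM against at most 1.66 CPM elsewhere, and how much of that sample was tumour was not measured.

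A run of genes around Met was high in Synapsin-cre replicate 2 and NG2-creERTM replicate 3. Of 1000 shuffles 0 were as high, but this follows from how a run was defined and does not weigh a chance order of genes. The margin does argue against a chance order. The highest shuffled running median was 2.498 in Synapsin-cre replicate 2, where the real one was 5.637. In NG2-creERTM replicate 3 the highest shuffled value was 2.898, and the real one was higher than in Synapsin-cre replicate 2. Transcription reading on from Met is argued against, because genes on the other strand were raised too, by a median log2 ratio of 4.64. More DNA copies of the region could give such a run, but that explanation is undecided. The medians of the flanking genes reached -0.69 and 0.61, outside the range set for it before the test, and no DNA was measured.

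Schwann and neural crest genes lay above Nestin-creERT2 in both other models. The sex of the animals stays open: Foxd3 was at 18.2 CPM in NG2-creERTM replicate 2, which had Xist at 1320 CPM, against at most 0.277 CPM in Nestin-creERT2, and Erbb3 at 143 CPM (at most 8.08) and the mean log2 CPM of the Schwann list at 3.65 (0.79 to 1.99) also speak against it. That is 1 library, however, and in Synapsin-cre sex-linked genes coincide with the model. Synapsin-cre replicate 1 alone is argued against, with camera adjusted p = 0.000668 without it (adjusted p = 0.357 with an estimated correlation), a fit in which Foxd3 rose (log2 fold change 8.21, edgeR adjusted p = 0.0198). Not all Schwann genes were higher. Prx overlapped, at 2.77 to 7.73 CPM in Nestin-creERT2, 1.81 to 11.998 CPM in Synapsin-cre and 5.83 to 14.6 CPM in NG2-creERTM. Pmp2 was nearly absent, at no more than 0.0277 CPM in any library. Erbb3 also stands in the proneural list. A tumour cell state with neural crest genes and non-tumour Schwann cells were not told apart.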

How the results depend on the processing

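The fits of 2 models that also left Synapsin-cre replicate 1 out, and the splits of the 6 libraries fitted alone, are tests chosen after the result was seen, and so was the weight given to the fit without that replicate.

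Gene counts depended on the tool and on Synapsin-cre replicate 1. Against 0 in edgeR for every comparison, no low-count filter gave 12 genes for Synapsin-cre against Nestin-creERT2, 12 for NG2-creERTM against Nestin-creERT2 and 23 among the 3 models, and DESeq2 gave 497, 623, 446 (Synapsin-cre against NG2-creERTM) and 868. Sample quality weights gave 266, 160 and 94 for the first, the second and the 3 models. Fits of 2 models only gave 5 and 237, the unstranded counts gave 1 (Foxd3) for Synapsin-cre against Nestin-creERT2, and 2 models leaving Synapsin-cre 1 out gave 431 and, against NG2-creERTM, 1. Leaving out 1 library gave 0 to 273 for Synapsin-cre against Nestin-creERT2, 0 to 124 for NG2-creERTM against Nestin-creERT2, 0 to 1 for Synapsin-cre against NG2-creERTM and 0 to 346 among the 3 models, each highest without Synapsin-cre replicate 1. The variance explained by model ran from 33.4 to 50.8% (42.1% without Synapsin-cre replicate 3). With 1 library left out, lists called ran from 17 to 25, 15 to 21 and 9 to 14 in the 3 comparisons. Without a filter they were 28, 19 and 18. With all 9 libraries they were 0 with camera at an estimated correlation and 0 with fry in all 3, and without Synapsin-cre replicate 1 they were 0 at an estimated correlation and 3, 3 and 0 with fry. The cause was not tested.

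Splits of the libraries of 2 models number 10, too few for a share under 0.05. For Synapsin-cre against Nestin-creERT2, 10 of 10 groupings had at least as many genes (0, highest other 1) and 3 as many lists (20, highest other 23); for NG2-creERTM against Nestin-creERT2, 10 (0, 0) and 2 (17, 19); for Synapsin-cre against NG2-creERTM, 10 (0, 0) and 9 (11, 23). With 6 libraries of NG2-creERTM and Nestin-creERT2, 1 of 10 groupings did, the real one (237, highest other 1). For the 3 models, 100 of 100 drawn groupings had at least the real 0 (highest other 6). Any grouping reaches a count of 0, so the gene counts of all 9 libraries say nothing on chance.

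Of 242 gene fold changes 27 changed sign in some fit, with 66 such values, of which 40 came from leaving out 1 library. None of the 27 had passed with all 9 libraries (lowest adjusted p 0.357), but no gene did there, so this does not show that passing genes keep their sign. Ralyl reversed without Synapsin-cre replicate 1 in Synapsin-cre against Nestin-creERT2 and passed in that fit (edgeR adjusted p = 0.0293). For NG2-creERTM against Nestin-creERT2, leaving out 1 library moved Nes from 0.01 (range -0.45 to 0.24), Pdgfra from -0.09 (-0.79 to 0.71), Hba-a1 from 0.51 (-0.18 to 3.27), Cspg4 from 0.76 (-0.14 to 1.98), Hbb-bs from 0.70 (-0.014 to 2.82) and Nf1 from 0.28 (-0.20 to 0.48). For Synapsin-cre against Nestin-creERT2 it moved Syn1 from 1.23 (-1.59 to 1.66), Hoxc4 from -1.80 (-2.39 to 0.95), Ralyl from 0.49 (-7.26 to 0.98), Cspg4 from -0.13 (-1.05 to 1.09), Nes from -0.24 (-0.69 to 0.26), Pcna from -0.37 (-1.04 to 0.022), Ccna2 from -0.47 (-1.67 to 0.059), Stmn2 from -0.22 (-2.29 to 0.25), Mmp14 from 1.06 (-0.0074 to 1.52), Trp53 from 0.95 (-0.29 to 1.34), Gfap from -0.19 (-1.18 to 0.30) and Tubb3 from -0.53 (-0.98 to 0.017). For Synapsin-cre against NG2-creERTM it moved Trp53 from 0.38 (-0.86 to 0.77), Hoxc4 from -3.33 (-3.93 to 2.98), Hoxd8 from -3.73 (-7.68 to 3.40), Nes from -0.26 (-0.70 to 0.25), Calb2 from 5.50 (-0.060 to 5.995), Egfr from -0.16 (-1.89 to 0.26), Cx3cr1 from -0.07 (-2.61 to 0.35) and Ly86 from -0.41 (-3.34 to 0.042).

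Among lists the mean log2 fold change ran from -2.92 to -0.32 for Hox genes (-1.92 with all libraries, camera direction up without Synapsin-cre replicate 1) and from -1.56 to 0.41 for proliferation (-0.69) in Synapsin-cre against Nestin-creERT2. It ran from -1.10 to 0.085 for ribosomal protein genes (-0.51) in Synapsin-cre against NG2-creERTM.

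Other settings turned fewer genes. For NG2-creERTM against Nestin-creERT2, Nes was -0.0078 with upper quartile size factors, -0.022 with no low-count filter, -0.077 with limma voom and -0.017 with quality weights, and Pdgfra 0.11 with limma voom and 0.013 with quality weights. For Synapsin-cre against Nestin-creERT2, limma voom gave Syn1 -0.092, Hoxc4 0.070 and Ralyl -3.98, and quality weights gave Syn1 -1.05, Hoxc4 0.74, Ralyl -5.92 and Cspg4 0.27. The fit of 2 models leaving Synapsin-cre 1 out gave Syn1 -1.58, Ralyl -7.25, Cspg4 0.37, Nes 0.26, Pcna 0.026 and Ccna2 0.062. For Synapsin-cre against NG2-creERTM, limma voom gave Trp53 -0.051. Quality weights gave Trp53 -0.14, Hoxc4 0.37, Hoxd8 0.41 and Sparc 0.18, and 2 models leaving Synapsin-cre 1 out gave Nes 0.22 and Calb2 -0.084.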

Other observations

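The tests for runs of neighbouring genes, and all genes named here, were chosen after the result was seen.

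Runs of raised genes, which by definition lay above all 1000 shuffles, were found in 5 of 9 libraries. NG2-creERTM replicate 2 had 23 genes on chromosome 3 (running median log2 ratio 3.14) with Pik3ca, a catalytic subunit of PI3-kinase, at 745 CPM, and 10 genes on chromosome 15 (2.91) with the oncogene Myc at 348 CPM. In the other libraries Pik3ca ran from 91.7 to 438 CPM, highest in Nestin-creERT2 replicate 3. Myc ran there from 20.7 to 253 CPM, highest in Synapsin-cre replicate 3. Nestin-creERT2 replicate 2 had runs of 8 and 6 genes on chromosome 8 (3.16 and 3.24), and Irs2, an insulin receptor substrate gene that lies between these runs and belongs to neither, at 370 CPM. Whether DNA copies were gained was not measured.

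Synapsin-cre replicate 1 differed from the other tumours in further genes. Cdkn2a, a cell cycle inhibitor locus, was at 2.43 CPM there against 84.9 to 289 CPM elsewhere, and Mki67, a gene of dividing cells, at 29.3 CPM against 347 to 672 CPM. Sox10, a factor of oligodendrocyte and neural crest lineages, was at 145 CPM, against 921 and 1090 CPM in Synapsin-cre replicates 2 and 3. That level lay within the Nestin-creERT2 range of 25.7 to 380 CPM. Foxd3 was nonetheless at 38.1 CPM, against at most 0.277 CPM in Nestin-creERT2.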
